A study of Saccharomyces cerevisiae with 28 samples.

How the data were processed

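The series profiled RNA of budding yeast (Saccharomyces cerevisiae) by RNA sequencing in 28 samples. The 10 libraries analysed here came from steady-state cultures: strain YL388 at 9 glucose concentrations (0.4, 0.2, 0.15, 0.1, 0.075, 0.05, 0.025, 0.02 and 0.0125%) and strain YL390 at 0.2% glucose, with 1 library each. Per the labels' protocols the cells were first grown in 0.2% glucose and then held for 2 h at the stated concentration. The other 18 samples, transient stress experiments in 3 strains, were not analysed here. Samples were grouped by the strain number and the glucose concentration in their labels. The labels give the strains by number and state no genotype.

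The deposited values are FPKM (fragments per kilobase of gene length per 1e6 mapped fragments) with a lower and an upper confidence bound, as estimated for each gene in Cufflinks output per the file headers. The submitters' processing notes name TopHat, Cufflinks, DESeq2 and the genome build sacCer3, without versions, options or the step each was used for. The gene annotation and whether fragments were counted by strand are not given in the sources used here. Each file held 6692 gene identifiers, of which 6008 were matched by systematic name to the RefSeq annotation of the R64 assembly, 6000 of them with identical coordinates. The length of a gene was taken as the span from its start to its end in the files, introns included, and was a multiple of 3 for 96.6% of the genes. Of all genes, 1321 (19.7%) overlapped another gene in the files. Chromosomes and positions below are those of the deposited files on sacCer3, counted from 1.

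No library total was used, because the files give no fragment counts. The width of the confidence bounds was read as 2 Poisson standard deviations on each side of the centre for genes over 1500 bp with over 50 implied fragments and no overlap. This reading implied 5.9 to 9.2 M fragments (M, 1e6) per library, and it covers counting error only. Between 6111 and 6158 genes had a value above 0 in a library, with a median over all genes of 43.4 to 49.1 FPKM. The FPKM column lay above its own upper bound for 45.3 to 53.2% of the genes above 0. The ratio of the FPKM to the centre of its bounds was 4.49 in the median for genes up to 300 bp and 1.00 for the longest genes. The 78 bp gene RPL41A, for example, was listed at 739402 FPKM with bounds of 8416 and 8888 at 0.4% glucose. The FPKM of short genes is therefore high relative to its bounds, and levels should not be compared between short and long genes, while comparisons of a gene with itself between libraries are less affected. Exact zeros also appeared for genes with 10 FPKM or more in other libraries (168 genes), so an exact 0 is reported below as listed at 0 and no fold of a named gene is given against it. The counts of genes over all values do include such genes, unless they are said to be left out.

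All fits used log2(FPKM + 1), and every fold change below is on that scale, which understates changes of genes at low values. Genes with a mean of at least 1 FPKM over the libraries of a fit were kept. The glucose trend was a slope on log2 glucose over the 9 YL388 libraries, fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The change given for a gene is the slope times the 5 doublings between 0.0125 and 0.4%, as the level at the lowest minus that at the highest concentration, with its standard error. Because no concentration was replicated, the error is the scatter of the 9 libraries around the line, and nothing states whether cultures were separate biological samples. Curves added the square of log2 glucose, both centred. A gene with a square term past the threshold and a vertex inside the measured range was called a peak or a trough. The strains were compared at 0.2% glucose, the only concentration measured in both, as a difference between 2 single libraries without a p-value, and genes with a difference of at least 2-fold and a mean of at least 1 FPKM were counted. A second fit over all 10 libraries asked whether the YL390 library lay off the YL388 curve, assuming that it varies like the YL388 libraries. That fit speaks of this library, not of the strain.

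Before the data were examined, 28 gene lists were fixed, of which 27 had enough members with a value to be tested. The list of genes of the mitochondrial genome was not tested for that reason. Lists were tested for the glucose slope with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists, again with an estimated correlation, and with fry. Camera compares the members of a list with all other genes, so its directions are relative to them, while fry tests the members alone. For the strain comparison, the median of a list was placed among 10000 random lists of the same size matched on mean expression, and a list below percentile 2.5 or above 97.5 was said to stand apart. The genes named were also fixed by rule: the 10 steepest slopes per direction among called genes with a mean of at least 10 FPKM and a sign that held with each library left out, the 5 largest square terms per direction, the 10 largest strain differences per direction with a mean of at least 10 FPKM, the 2 steepest members per list and direction, and all members of the list of glucose regulators. Genes named outside this rule are marked as chosen after their values were seen. Gene sequences, introns included, were searched against the R64 genome with BLAST 2.17.0+ for other places of at least 95% identity over at least 80% of the length, and such genes are named with that limit.

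The fits were tested on simulated data built on the values of these libraries, with 100 genes changed by 1 and 100 by 2 on the log2 scale. The trend recovered 88% and 93% of them with 9 false among 190 calls over 6108 genes. The curve recovered 89% and 94% with 4 false among 187 calls over 6110 genes. The departure of a single library recovered 83% and 91% with 11 false among 185 calls over 6102 genes. In the list test, a ribosomal protein list shifted by 0.5 was called and 0 of 26 other lists were. The simulated genes varied independently of each other, whereas the estimated inter-gene correlation of this list in the data was 0.663. The simulation therefore does not show how the list test behaves at the preset correlation when genes vary together. Alternatives tried were pseudocounts of 0.1 and 10, no filter or one at 10 FPKM, median-of-ratios scaling, quantile normalization, other glucose scales, a robust fit without a trend, each library left out in turn, and other references and criteria for the strain comparison. After the data were seen, the centre of the confidence bounds in place of the FPKM, the removal of overlapping genes and of genes listed at 0 in some libraries, quantile normalization for the lists, and a minimum turn of 0.5 for peaks and troughs were added.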

Results

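RNA of budding yeast was sequenced from steady-state cultures of the strain YL388 at 9 glucose concentrations from 0.4 down to 0.0125%, a 32-fold range, and of the strain YL390 at 0.2% glucose. Each culture gave 1 library, so no concentration and neither strain had a replicate. The series is about how the relative timing of pulses of regulator activity sets gene expression, and from what is known of the study the regulators in question are Msn2, an activator of stress genes, and Mig1, a repressor of genes for the use of other sugars, which both respond to glucose. The steady-state libraries address how transcript levels depend on the glucose concentration, and how the YL390 culture differed from the YL388 culture at a shared concentration. The confidence bounds in the files implied 5.9 M fragments (M, 1e6) in the shallowest library (YL388 at 0.15%) and 9.2 M in the deepest (YL390). The YL388 libraries scattered little around smooth curves over glucose, with a median residual SD of 0.088 on the log2 scale.

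As glucose fell from 0.4 to 0.0125%, genes for the use of poorer carbon sources, respiratory genes and Msn2 and Msn4 target genes rose, and genes for making ribosomes fell. These list calls were made by camera at its preset correlation, and 0 of 27 lists were called with an estimated one. The transcript of SUC2, the invertase that splits sucrose (YIL162W, chromosome IX, 37385 to 38983), rose from 54.8 to 554.5 FPKM, a fitted log2 change of 3.66 ± 0.50 (SE, n = 9 libraries; limma adjusted p = 0.000585). JEN1, the lactate permease, rose from 8.47 to 220.7 FPKM, by 4.45 ± 0.57 (limma adjusted p = 0.000461). In the other direction, HXT2, a glucose transporter (YMR011W, chromosome XIII, 288079 to 289704), fell from 793.5 to 151.6 FPKM, a log2 change of -2.18 ± 0.39 (limma adjusted p = 0.00189). SUC2 rose mostly below 0.05% glucose and stood at 89.9 FPKM at 0.05% and at 287.5 FPKM at 0.025%.

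Of 6121 genes tested, 1937 rose and 958 fell towards lower glucose, 47.3% of the genes in all. The change reached 2-fold for 460 of the genes that rose and for 63 of those that fell. The deposited values carry a shift of their own, since the median change over all genes was 0.117 on the log2 scale. Median-of-ratios scaling, which takes this shift to 0, gave 1409 genes that rose and 1399 that fell, and quantile normalization gave 1213 and 1738, so the balance between the directions is set by the scaling. With glucose in percent in place of its logarithm as the scale, 0 genes passed in limma in either direction, against 2895 on the log scale. At an unadjusted p under 0.05 there were 1914 genes on the percent scale and 3317 on the log scale.

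Among the steepest genes, SIP18, a hydrophilin of desiccation tolerance, rose from 208.3 to 13040 FPKM (log2 change 5.95 ± 0.92, limma adjusted p = 0.00105). RGI2, a gene of respiratory growth, rose from 0.27 FPKM, near the floor, to 740.1 FPKM. SFC1, a mitochondrial succinate-fumarate carrier, went from 4.98 to 213.9 FPKM, and GRE1, a hydrophilin related to SIP18, from 30.9 to 1059 FPKM. SPG4, a gene of stationary phase survival, rose from 40.2 to 1212 FPKM and PAI3, an inhibitor of proteinase A, from 344.5 to 9459 FPKM. The steepest genes that fell and were above 0 in every library were HXT2, INA1 (152.5 to 34.7 FPKM), HXT3, YNL303W and YDR524C-A, of which YNL303W and YDR524C-A overlap another gene. YKL106C-A and YBR103C-A, short genes that the rule also named, were each listed at 0 in 1 library. The other 7 genes named by the steepest slopes (RPL36B, YIL020C-A, YBR116C, YFL031C-A, YMR304C-A, YER088C-A and YDR008C) overlap another gene and were listed at 0 in some libraries, and no change is given for them.

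The genes repressed by Mig1 mostly rose: of 17 tested, 14 rose, 2 fell and 1 was not called, with the same counts when adjusted over the list alone, and a median log2 change of 1.54 (camera adjusted p = 0.000719, and adjusted p = 0.374 with an estimated correlation). SUC2 and JEN1 were the steepest of them. The members that fell were both hexose transporters, HXT2 and HXT4 (34.1 to 22.5 FPKM). The galactose and maltose genes had 10 of 14 members that rose and 0 that fell, also when adjusted over the list alone, with GAL3, the galactose sensor, going from 7.56 to 25.3 FPKM and the maltose activator MAL33 from 16.9 to 57.0 FPKM (camera adjusted p = 0.00738, and adjusted p = 0.374 with an estimated correlation). Quantile normalization left 5 of these that rose and 1 that fell.

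All 34 tested Msn2 and Msn4 target genes rose, and all 34 did when adjusted over the list alone, with a median log2 change of 2.07 (camera adjusted p = 6.7e-12, and adjusted p = 0.388 with an estimated correlation). The small heat shock protein gene HSP26 went from 23.9 to 331.5 FPKM with SIP18 as the only steeper member. HSP12, which encodes an abundant membrane-stabilising stress protein and was chosen here after its values were seen, rose from 13690 to 50470 FPKM (log2 change 1.87 ± 0.29, limma adjusted p = 0.000999). Of 20 genes for trehalose and glycogen, 9 of them also target genes, 19 rose, and the median over all 20 was 1.18 (camera adjusted p = 2.39e-07, and adjusted p = 0.374 with an estimated correlation), and adjusted over the list alone the count was also 19. The glycogen branching enzyme gene GLC3 rose from 23.1 to 99.5 FPKM. Glycogen phosphorylase, GPH1, which overlaps another gene, rose from 23.2 to 85.7 FPKM.

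Most or all members of the lists for oxidative metabolism rose. In gluconeogenesis and the glyoxylate cycle, 23 of 24 genes rose, and the median over all 24 was 1.78 (camera adjusted p = 1.02e-06, and adjusted p = 0.444 with an estimated correlation), with SFC1 and JEN1 the steepest. All 15 tricarboxylic acid cycle genes rose by a median of 1.67 (camera adjusted p = 2.39e-07, and adjusted p = 0.388 with an estimated correlation), including the succinate dehydrogenase genes SDH4 (300.5 to 1391 FPKM) and SDH1 (116.2 to 464.2 FPKM). All 34 nuclear genes of the respiratory chain rose by a median of 1.17 (camera adjusted p = 5.01e-12, and adjusted p = 0.388 with an estimated correlation), led by the external NADH dehydrogenase gene NDE2 (5.80 to 45.3 FPKM) and by CYB2, the lactate dehydrogenase (26.6 to 116.7 FPKM). Of 15 genes for peroxisomal fatty acid oxidation 14 rose, and the median over all 15 was 1.15 (camera adjusted p = 9.89e-05, and adjusted p = 0.444 with an estimated correlation), and adjusted over the list alone all 15 did. For the other 3 groups the counts adjusted over the list alone were again 23, 15 and 34.

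Genes of protein synthesis fell, by smaller amounts. All 60 ribosome biogenesis genes fell, also when adjusted over the list alone, by a median log2 change of -0.75 (camera adjusted p = 6.82e-27, and adjusted p = 0.374 with an estimated correlation), with the helicase genes DBP2 (217.3 to 61.7 FPKM) and DHR2 (26.0 to 9.91 FPKM) in front. Of 138 ribosomal protein genes, 113 fell, 3 rose and 22 were not called, and adjusted over the list alone 122 fell and 4 rose (median -0.53, camera adjusted p = 6.71e-28, and adjusted p = 0.374 with an estimated correlation). RPL9A went from 3251 to 1623 FPKM. RPL1B went from 660.3 to 313.6 FPKM, but it is 99.4% identical to RPL1A, and how reads were divided between them is not known.

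Amino acid genes of the general control response moved both ways, with 17 of 44 that fell and 5 that rose, the same when adjusted over the list alone (camera adjusted p = 9.89e-05, and adjusted p = 0.374 with an estimated correlation). HIS1 of histidine synthesis fell from 391.8 to 193.6 FPKM, while CPA1 of arginine synthesis rose from 585.0 to 819.5 FPKM. In sulfate assimilation and methionine synthesis 6 of 22 genes fell and 2 rose, also when adjusted over the list alone, with SAM1, an S-adenosylmethionine synthetase, going from 399.2 to 125.5 FPKM (camera adjusted p = 0.0333, and adjusted p = 0.559 with an estimated correlation). Of 17 haploid mating genes 8 fell and 3 rose, or 9 and 3 adjusted over the list alone, and the regulator gene SST2 of the pheromone response fell from 64.3 to 30.8 FPKM (camera adjusted p = 0.0015, and adjusted p = 0.374 with an estimated correlation). Iron uptake had 11 of 15 genes that rose, or 12 adjusted over the list alone, with the cell wall proteins FIT2 (51.7 to 176.4 FPKM) and FIT3 (39.7 to 134.7 FPKM) the steepest (camera adjusted p = 0.005, and adjusted p = 0.374 with an estimated correlation). Among genes for poor nitrogen sources 12 of 21 rose, or 13 adjusted over the list alone, among them the glutamate dehydrogenase GDH2 (24.6 to 92.7 FPKM) and the proline permease PUT4 (116.5 to 330.3 FPKM) (camera adjusted p = 0.0333, and adjusted p = 0.388 with an estimated correlation). These counts depend on the scaling. With quantile normalization 7 of the nitrogen genes rose and 3 fell, 7 iron genes rose, 2 amino acid genes rose and 27 fell, 1 methionine gene rose and 10 fell, and 1 mating gene rose and 11 fell.

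In all, camera called 17 of the 27 lists at the preset correlation, 11 that rose and 6 that fell relative to the other genes, and 0 with an estimated correlation. Fry, which tests the members alone, called 19 but neither methionine synthesis (fry adjusted p = 0.213) nor cell separation (fry adjusted p = 0.0917).

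Glycolysis was not called as a list by camera (camera adjusted p = 0.249), and its median change was 0.00 with 4 of 19 genes that rose, 3 that fell and 12 not called, or 3 and 3 adjusted over the list alone. Its mean change was 0.09 while its test pointed down, which is relative to the other genes (the median change over all genes was 0.117). TDH1, a glyceraldehyde-3-phosphate dehydrogenase, rose from 16.0 to 65.0 FPKM and the enolase ENO1 from 90.2 to 375.9 FPKM. The other enolase, ENO2, fell from 2319 to 1207 FPKM, and pyruvate kinase, CDC19, from 1823 to 1037 FPKM. CDC19 overlaps another gene. Heat shock chaperones were also split (11 rose, 4 fell and 8 were not called of 23, or 12 and 5 adjusted over the list alone, camera adjusted p = 0.806): the small heat shock protein gene HSP42 went from 65.0 to 227.9 FPKM, whereas SSA2 fell from 444.2 to 188.4 FPKM and YDJ1 from 676.5 to 414.7 FPKM. SSA2 is 96.4% identical to SSA1. Of 15 peroxide defence genes 7 rose and 3 fell, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.806), with the mitochondrial superoxide dismutase SOD2 going from 492.4 to 1501 FPKM and the oxidoreductase OYE2 from 162.0 to 98.0 FPKM. The lists for phosphate starvation, sterol and fatty acid synthesis, the G1 to S phase, histones, G2 and mitosis, and meiosis were not called by camera either, with 4 of 14, 5 of 27, 2 of 19, 4 of 8, 1 of 13 and 4 of 18 members that rose. With quantile normalization the balance turned for sterol and fatty acid synthesis (from 5 that rose and 1 that fell to 3 and 9) and for meiosis (from 4 and 0 to 1 and 3), and phosphate starvation had 1 and 1. The tests of the G1 to S and the G2 and mitosis lists pointed down relative to the other genes, with medians of 0.05 and 0.09. By fry, phosphate starvation (adjusted p = 0.00719), sterol and fatty acid synthesis (0.00758), meiosis (0.0485) and peroxide defence (0.000227) were called, and camera called histones under quantile normalization (adjusted p = 0.0162).

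**Figure D1:**
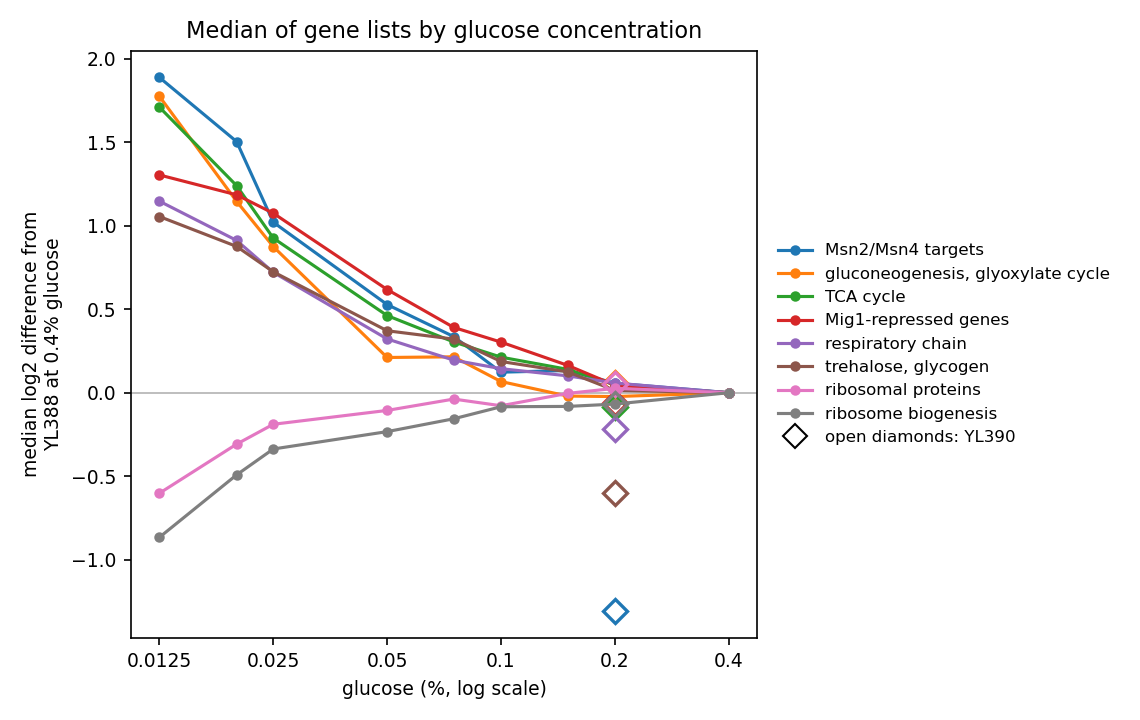
Median log2 difference of 8 gene lists from the YL388 library at 0.4% glucose, on log2(FPKM + 1), against glucose in percent on a log axis. Lines join the 9 single YL388 libraries and open diamonds are the YL390 library at 0.2%. The Msn2 and Msn4 target list stands at 1.89 in the library at 0.0125% and at -1.31 in the YL390 library.

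Regulators of glucose signalling were measured whatever their values. Of 24 tested, 14 rose, 2 fell and 8 were not called, and adjusted over the list alone 15 rose and 2 fell (camera adjusted p = 0.0282, and adjusted p = 0.498 with an estimated correlation). The rise with the smallest adjusted p was in USV1, a zinc finger regulator, from 85.6 FPKM at 0.4% to 232.4 FPKM at 0.0125% (log2 change 1.46 ± 0.08, limma adjusted p = 4.5e-05). CAT8 and ADR1, activators of genes for non-fermentable carbon, went from 5.34 to 14.96 FPKM and from 19.8 to 38.0 FPKM, and HAP4, the activator of respiratory genes, from 93.5 to 236.1 FPKM. The protein kinase A subunit gene TPK3 fell from 78.3 to 57.7 FPKM. The glucose sensor gene SNF3 rose from 12.1 to 21.3 FPKM, and STD1, a cofactor of the repressor Rgt1, fell from 29.6 to 14.96 FPKM, while MTH1, the related cofactor, rose from 67.0 to 102.1 FPKM. MSN2 and MIG1 themselves were not called. MSN2 lay between 37.8 and 46.6 FPKM in the 9 YL388 libraries, and MIG1 between 76.0 and 102.7 FPKM. MSN4, the paralog of MSN2, lay between 0.69 and 1.70 FPKM. MIG2, NRG1 and NRG2 were listed at 0 in every library of both strains.

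A straight line cannot show that the level of a gene turned at an intermediate concentration. HXT3, a low-affinity glucose transporter (YDR345C, chromosome IV, 1162957 to 1164660), fell from 91.1 FPKM at 0.4% to 14.5 FPKM at 0.05% and stood at 24.0 FPKM at 0.0125% (square term 0.242, limma adjusted p = 3.7e-05). HXT1, named after its values were seen, went from 31.8 FPKM at 0.4% to 10.3 FPKM at 0.025% and 19.3 FPKM at 0.0125% (limma adjusted p = 0.00502 for the square term), but this call rests on the library at 0.4%, without which the adjusted p was 0.0946. Of 11 hexose transporter and sensor genes, 4 rose, 3 fell and 4 were not called on the straight line, the same when adjusted over the list alone. The list was not called (camera adjusted p = 0.806), and its test pointed down relative to the other genes while its median (0.06) and mean (0.32) were above 0. HXT5, a transporter of slow growth, rose from 11.02 to 85.6 FPKM. HXT7, a high-affinity transporter, rose from 79.2 FPKM to 235.4 FPKM at 0.025% and stood at 182.0 FPKM at 0.0125%. HXT7 is 99.8% identical to HXT6, so reads of this pair cannot be divided with certainty.

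The curve fit called 451 genes with a peak and 481 with a trough. Most of these curves bent without turning far: the fitted turn reached 0.5 on the log2 scale, a limit chosen after the data were seen, for 19 of the peaks and 10 of the troughs, and for 6 and 7 of them without genes that overlap another or were listed at 0 in some libraries. The 5 troughs named by rule (SIP18, RGI2, SFC1, SPG4 and IDP2) were of this bending kind, with little change down to 0.1% and then a steep rise, apart from RGI2, which was near the floor there. IDP2, a cytosolic isocitrate dehydrogenase, for example stood at 15.7 FPKM at 0.4%, at 18.1 FPKM at 0.1% and at 403.8 FPKM at 0.0125%. The call of RGI2 was lost without the library at 0.4% (limma adjusted p = 0.0727 for the square term). SPG4 was not called as a trough without that library either, although its square term passed in every such fit (limma adjusted p = 0.00949 at most). Troughs made up 29 of the 34 respiratory chain genes, 23 of the 34 target genes and 18 of the 24 gluconeogenesis genes, and peaks 67 of the 138 ribosomal protein genes and 35 of the 60 ribosome biogenesis genes. Without the library at 0.0125% these peaks fell to 7 ribosomal protein and 1 ribosome biogenesis genes, and without the one at 0.4% to 4 and 14. The troughs fell to 20 respiratory chain, 18 target and 10 gluconeogenesis genes without 0.0125%, and to 13, 15 and 8 without 0.4%. The peaks named by rule included YLR444C, YHR063W-A, YDL050C and YDR413C, which overlap another gene and were listed at 0 at 0.4% glucose, and no change is given for them.

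Among genes for the separation of daughter cells, 6 of 11 were called as peaks, 3 of them with a turn of at least 0.5. The 6 fell to 3 without the library at 0.075% and to 4 without the one at 0.4%. DSE2, a glucanase gene of the daughter cell wall, stood at 365.9 FPKM at 0.4%, at 582.0 FPKM at 0.05% and at 339.4 FPKM at 0.0125% (limma adjusted p = 0.0188 for the square term). SCW11, a cell wall protein of the same kind, went from 120.1 to 166.6 and back to 74.5 FPKM at these concentrations, and SUN4, a further cell wall gene chosen with DSE2 and SCW11 after the values were seen, from 205.3 to 282.6 and 127.9 FPKM. On the straight line the list was called as falling (camera adjusted p = 0.00388, and adjusted p = 0.486 with an estimated correlation), although only 3 of the 11 genes fell singly, PIR1 (974.3 to 218.8 FPKM), EGT2 (132.9 to 48.1 FPKM) and CLN3, the last named after its values were seen, and 0 did when adjusted over the list alone. The peaks and troughs depend on single libraries: without the library at 0.0125% there were 77 peaks and 218 troughs, and without the one at 0.4% 174 and 147. The call of SCW11 was lost without the library at 0.0125% and that of DSE2 without the one at 0.4 or at 0.075%, while SUN4 and HXT3 passed with each library left out.

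**Figure D2:**
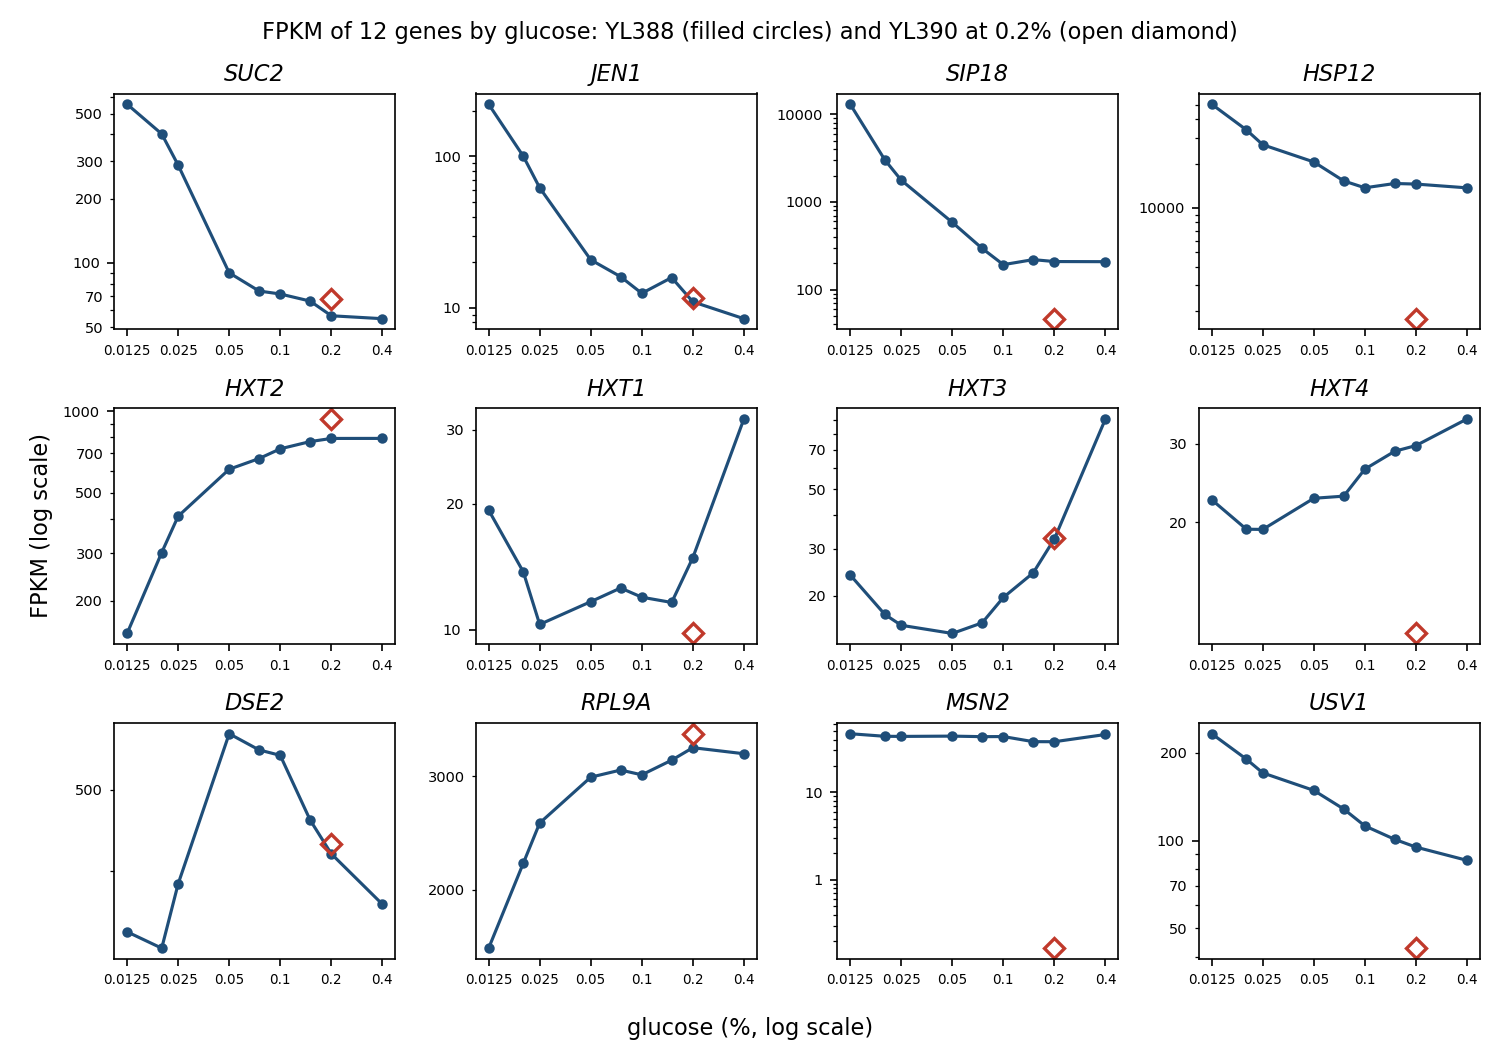
FPKM of 12 genes on log axes against glucose in percent, also on a log axis. Filled circles joined by lines are the 9 single YL388 libraries and the open diamond is the single YL390 library at 0.2%. SUC2 and JEN1 climb towards 0.0125%, HXT3 turns with a low of 14.5 FPKM at 0.05%, and MSN2 is flat in YL388 and at 0.17 FPKM in YL390.

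At 0.2% glucose the YL390 library stood out from the YL388 library by the transcript of MSN2 and by Msn2 and Msn4 target genes. MSN2 (YMR037C, chromosome XIII, 344403 to 346517) was at 37.8 FPKM in YL388 and at 0.17 FPKM in YL390, with Cufflinks bounds of 0.029 and 0.29 FPKM. The Msn2 and Msn4 target genes had a median log2 difference of -1.28 (YL390 minus YL388), below all 10000 random lists of matched expression (percentile 0.00). Of these 34 genes, 24 were at least 2-fold lower in YL390 and 0 at least 2-fold higher, and 33 lay below each of the 9 YL388 libraries. Genes repressed by Mig1 did not stand apart as a list, with a median difference of -0.01 (percentile 10.3). Of 15 compared, 3 were at least 2-fold lower in YL390 and below the YL388 curve and 0 were 2-fold higher: HXT4, and HXK1 (434.6 and 69.3 FPKM) and EMI2 (71.6 and 33.7 FPKM), both hexose kinase genes named after their values were seen. HXK1 overlaps another gene and is also on the target list. SUC2 was at 56.6 FPKM in YL388 and 68.2 FPKM in YL390, and JEN1 at 10.95 and 11.6 FPKM.

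The genes furthest lower in YL390 among those without an overlap and above 0 in all libraries, a ranking chosen after the data were seen, were MSN2 and 9 genes that rose at lower glucose in YL388. YGP1, a secreted glycoprotein of nutrient limitation (YNL160W, chromosome XIV, 336545 to 337609), was at 457.8 FPKM in YL388 and 37.7 FPKM in YL390, 11.8-fold lower. RTC3 was 8.56-fold lower, HSP12 8.17-fold lower (14520 and 1777 FPKM) and DDR2, a DNA damage and stress gene, 7.73-fold lower. The trehalose synthase subunit gene TSL1 was 5.71-fold lower, HOR7 5.52-fold, SOL4 5.37-fold and STF2, a gene of desiccation tolerance, 4.71-fold lower. The remaining gene was the short YCL048W-A. SIP18 was at 209.0 and 46.6 FPKM. In the other direction the largest differences were in the short genes YMR001C-A (9.36-fold higher) and MIN4 (6.94-fold higher), neither of which was called as off the YL388 curve. The 10 largest included only 2 genes over 600 bp, ARG3 of arginine synthesis (18.8 and 44.2 FPKM) and ARO10, a decarboxylase of aromatic amino acid breakdown (62.3 and 137.0 FPKM). The original ranking named mostly overlapping genes listed at 0 in either the YL388 or the YL390 library, such as RPL36B, YLR076C, YFL031C-A and YBR126W-B. With all genes counted, 79 of 6072 genes were at least 2-fold higher and 101 at least 2-fold lower in YL390. Without genes that overlap another or were listed at 0 in some libraries, 28 were higher and 62 lower.

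In the strain comparison 10 lists stood apart, 4 lower and 6 higher in YL390. Next to the target genes, the lower lists were trehalose and glycogen (median -0.63, percentile 0.00), the respiratory chain (-0.28, percentile 0.00) and the tricarboxylic acid cycle (-0.24, percentile 0.00). The difference in trehalose and glycogen came mainly from the 9 genes shared with the target list, since the 11 others had a median of 0.00 with 3 of them below the curve. The higher lists differed by little: G2 and mitosis 0.21, haploid mating 0.19, methionine synthesis 0.17, cell separation 0.17, heat shock chaperones 0.15, and sterol and fatty acid synthesis 0.13, each at percentile 99.33 or above. Few of their members lay above the YL388 curve: 2 in methionine synthesis, 2 in sterol and fatty acid synthesis, 1 in G2 and mitosis and 0 in the others. Relative to YL388 at 0.4%, the YL390 medians of cell separation (0.174), heat shock chaperones (0.190) and G2 and mitosis (0.069) lay within the range of the YL388 libraries, whose highest medians were 0.206, 0.428 and 0.156. The other higher lists lay above that range. Haploid mating stood at 0.131, methionine synthesis at 0.133 and sterol and fatty acid synthesis at 0.102, against highest YL388 medians of 0, 0.087 and 0.078. The lower lists lay below the lowest YL388 median of 0. Their YL390 medians were -1.308 (target genes), -0.6 (trehalose and glycogen), -0.217 (respiratory chain) and -0.087 (tricarboxylic acid cycle). Without overlapping genes and genes listed at 0 in some libraries, sterol and fatty acid synthesis moved to percentile 97.11 and no longer stood apart, which left 9 lists. Ribosomal proteins (median 0.01), ribosome biogenesis (0.01) and gluconeogenesis (0.11) did not stand apart. These percentiles describe 2 libraries and are not tests of the strains.

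The fit over all 10 libraries put 172 genes below and 52 above the YL388 curve in the YL390 library, with 59 and 6 of them off by at least 2-fold, out of 6120 tested and 903 at an unadjusted p under 0.05. Of the 34 target genes, 30 were below and 0 above. HSP12 was below by -2.92 ± 0.11 on the log2 scale (SE, limma adjusted p = 1.91e-06) and MSN2 by -5.18 ± 0.10 (limma adjusted p = 8.6e-08). The regulators below the curve included MSN2, USV1 (95.01 and 42.8 FPKM at 0.2% in YL388 and YL390) and HAP4 (94.5 and 70.4 FPKM). MSN4, at 0.92 and 1.63 FPKM, was not called (limma adjusted p = 0.677). Respiratory chain genes were below in 12 of 34 cases and tricarboxylic acid cycle genes in 4 of 15. HXT4 was the named hexose transporter furthest off, at 29.7 FPKM in YL388 and 11.2 FPKM in YL390, with a departure of -1.30 ± 0.11 (limma adjusted p = 0.000238). ARG3 was above by 1.08 ± 0.19 (limma adjusted p = 0.0178), and ARO10, 2.18-fold higher in YL390, was above as well (limma adjusted p = 0.0189). With a straight line in place of the curve, 64 genes were below and 20 above.

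**Figure D3:**
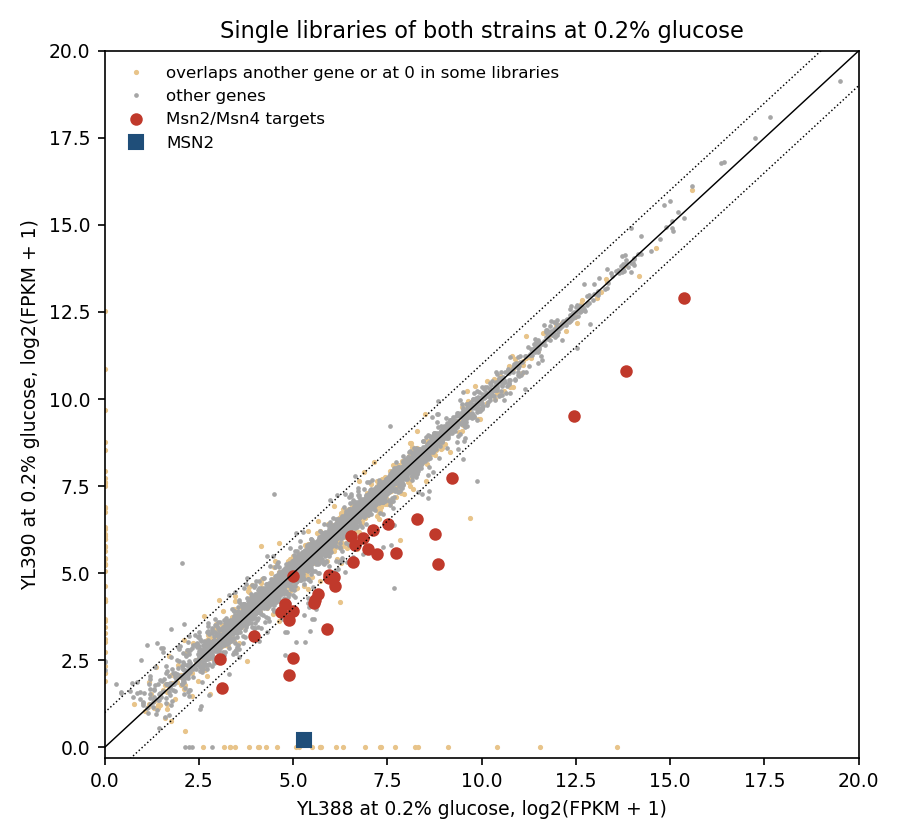
Expression in the single YL390 library against the single YL388 library, both at 0.2% glucose, as log2(FPKM + 1), with 1 point per gene. The solid line marks equal values and the dotted lines a 2-fold difference. Of the 34 target genes (red), 24 lie below the lower dotted line, and MSN2 (blue) is at 37.8 FPKM in YL388 and 0.17 FPKM in YL390.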

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

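The comparisons rest on single libraries, so each alternative moves the estimate of scatter as well as the values. The centre of the confidence bounds, the removal of overlapping genes and of genes listed at 0 in some libraries, quantile normalization for the lists, and the minimum turn were chosen after the data were seen. No paired analysis was possible because the steady-state groups hold 1 library each, and the transient libraries whose labels share replicate numbers were not analysed here. For the glucose trend, 20 of 22 alternatives kept the count in each direction within 1.5 times (1937 rose and 958 fell). Quantile normalization gave 1213 and 1738, and glucose in percent gave 0 and 0; that scale gives the library at 0.4% most of the weight. With each library left out the trend gave 1502 to 1949 and 671 to 974 genes. For peaks (451) and troughs (481), leaving out each library gave 77 to 415 and 147 to 465, lowest without 0.0125% and without 0.4%; these fits have 1 library less at an end or in the middle of the curve, and the cause was not tested further. A fitted turn of at least 0.5 gave 19 and 10. The strain counts (79 higher, 101 lower) became 45 and 67 with a pseudocount of 10, 47 higher with a filter at 10 FPKM, 28 and 62 without overlapping genes and genes listed at 0 in some libraries, 20 and 64 when the YL390 value also had to lie outside all 9 YL388 libraries, and 49 higher when the bounds also could not overlap. Each of these leaves fewer genes by its construction. With the mean of YL388 at 0.15, 0.2 and 0.4% glucose as the reference, 106 genes were higher and 96 lower. The balance between the directions thus turned with the reference. The departures (52 above, 172 below) became 20 and 64 with log2 glucose alone as the curve, for which the cause was not tested, and ranged from 31 to 68 and from 146 to 194 with each YL388 library left out. The lists called for the trend fell from 17 to 0 with an estimated correlation and ranged from 15 to 18 with each library left out; the 10 lists apart between the strains stayed within 1.5 times in all 6 alternatives. No named gene changed the sign of a called slope in any alternative run, and no named strain difference of at least 2-fold changed sign. With glucose in percent all named slopes lost their call. HXT3 (8 of 22 alternatives), PIR1 (8 of 22), EGT2 (11 of 22) and YDR524C-A (9 of 21) lost theirs most often among the genes named for falling. At the implied 5.9 to 9.2 M fragments (M, 1e6), genes near 1 FPKM such as MSN4 are too sparsely covered for small changes to be seen.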

Other observations

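The tests of the implied glucose shift, of a label exchange and of the genes listed at 0 in some libraries were chosen after those results were seen, as were the permuted sites and the model with the slope; the tests of upstream sites, of near-identical copies and of other orders of the libraries were set before their results were seen.

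Some genes outside the target list moved with it. STF2, a gene of desiccation tolerance, rose from 893.3 to 5653 FPKM over the glucose range and was at 199.6 FPKM in YL390, and SPG4 was at 38.2 FPKM in YL388 and 12.9 FPKM in YL390 at 0.2% glucose. The proline permease gene PUT4 was likewise lower in YL390 (106.0 and 57.3 FPKM), below the curve by -0.95 ± 0.11 (limma adjusted p = 0.00187), although the list for poor nitrogen sources did not stand apart between the strains (median 0.03, percentile 31.39).

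The order of the glucose values matters for the counts of calls. Of 100 orders of the 9 values, the real one included, 1 reached the 2895 trend calls, with at most 1 call in the others. Chance in the order is therefore excluded for the trend. Likewise 1 order reached the 932 peaks and troughs, with at most 1 in the others. Another order also breaks the straight-line trend, which then adds to the scatter around the curve. The orders therefore cannot decide whether the peaks and troughs arose by chance. Each of the 10 libraries taken in turn as the odd one gave 224 genes off the curve for YL390 and at most 37 for another, the YL388 library at 0.0125%. The fits for the YL388 libraries kept YL390 in as if it lay on the curve. Its departures then add to the scatter and can lower those counts, so 224 and 37 are not a like comparison. Only 1 of the 10 choices reached 224, and 10 choices are too few for a share under 0.05.

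The low target genes in YL390 were set against both a technical and a biological explanation. For a culture at more glucose than labelled, the strain difference was divided by each gene's straight-line slope. It implied 3.81 doublings of glucose for the 34 target genes (95% bootstrap interval over genes 2.69 to 4.90). For 93 other genes of the lists that rose it implied 0.35 (-0.09 to 0.64). The YL388 target median differed by only 0.057 between 0.4 and 0.2%, so a straight line does not hold there. Genes also vary together, which the intervals ignore, so the doublings cannot decide this explanation. Of the 34 target genes, 33 were lower in YL390 than in YL388 at 0.4%, the highest concentration measured. An exchange with a YL388 library would need such a library without MSN2, and the lowest of the 9 held 37.8 FPKM, while an exchange with a sample not analysed here remains open. The hypothesis that Msn2 activity was lower in the YL390 culture may account for the pattern. For this test, genes that overlap another, were listed at 0 in some libraries or lacked 500 bp of upstream reference sequence were left out. Among the 122 genes left below the curve outside the target list, 38.5% had at least 2 stress response elements (AGGGG on either strand) within 500 bp upstream. This compares with 14.9% of 610 genes of like glucose slope (odds ratio 3.57, Fisher's exact test p = 1.78e-08). The slopes were matched only in part (median log2 change 1.26 against 1.00), and with the slope in the model the odds ratio was 3.39 (2.20 to 5.23), against 1.46 (0.852 to 2.49) for a permuted element, GGAGG, in the same model. For Mig1 sites the odds ratio was 1.12 (Fisher's exact test p = 0.599, and 1.85 for the permuted site), which does not separate more repression by Mig1 from none. The MSN2 transcript itself was nearly absent from the YL390 library, while in YL388 it was not called for glucose. No genotype is stated and each strain has 1 library at 0.2% glucose. An effect of the strain and one of the culture therefore cannot be told apart.

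Upstream sites were also compared, with the same genes left out for overlap, zeros or missing upstream sequence, between 396 genes that rose at least 2-fold at lower glucose and 2574 genes not called. Unlike above, members of the Msn2 and Msn4 target list were kept in. Part of the difference in stress response elements may therefore come from how that list was chosen. At least 2 stress response elements were present in 27.0% against 5.63% (odds ratio 6.2, Fisher's exact test p = 7.04e-34), and the permuted element gave an odds ratio of 2.09. A Mig1 site was present in 40.4% against 20.0% (odds ratio 2.7), but its permuted form gave 2.86, so base composition may explain the Mig1 value and that test leaves a role of these sites open.

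Genes listed at 0 in some libraries and at 10 FPKM or more in others numbered 168. The median of their highest values was 63.4 FPKM, but the genes were chosen for reaching 10 FPKM and the FPKM of short genes is high relative to its bounds, so expression near the detection limit is left open. Overlap with another gene was present in 80.4% of them against 13.2% of 5952 other genes (odds ratio 26.9, Fisher's exact test p = 1.21e-82), which is consistent with reads being assigned to the overlapping gene in some libraries and not in others. The 33 without an overlap were at most 219 bp long. Whether the zeros depend on glucose was not tested, and no biological explanation was.

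Of 4276 genes of at least 600 bp without an overlap, 26 were under 0.1 FPKM in all 10 libraries. A near-identical copy was present for 80.8% of them (21 genes), against 1.2% of 4204 genes with a mean of at least 1 FPKM. Among the 21, as genes named after their values were seen, were the asparaginase genes ASP3-1 to ASP3-4 and the transporter gene HXT16. Reads shared with the copy may account for some of the 21. ASP3-1 to ASP3-4 were all listed at 0 with upper bounds of 0, so their reads were not moved from one of these genes to another. Whether shared reads were dropped is not known, and absence or silence of genes with a copy was not tested. The other 5, likewise named, were NRG1, NRG2, MIG2, URA3 and the mitochondrial gene VAR1, which have no copy and an upper bound of 0 in all libraries. NRG1, NRG2 and MIG2 encode repressors of glucose-repressed genes that act beside Mig1, and URA3 is a common selection marker, so a candidate explanation is that these nuclear loci are deleted in both strains. The 5 upper bounds of 0 would also be seen for silent genes, and absence and silence cannot be told apart from these values. Genotypes of the strains or reads over the loci would decide it for the nuclear genes. VAR1 differs from these, since the mitochondrial list matched 13 genes but too few of them had a value to be tested. Its 0 is thus not particular to this gene, and the cause was not tested.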
